A study of Gossypium barbadense and Gossypium hirsutum with 8 samples.

How the data were processed

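Total RNA of fibers from G. barbadense and G. hirsutum was sequenced as 8 Illumina libraries, 1 for each species at 5, 10, 15 and 20 DPA. The deposited table gives RPKM (reads per kilobase of gene, scaled to library size), made by the authors, with 2 decimals, for 59006 genes in 8 columns, all of which were used. The submitters' processing notes name cutadapt, Bowtie2 and edgeR, with no version or role. The genome build, the annotation, the treatment of reads that fit several genes and the library size used in the scaling are not given in the sources used here. The identifiers have the form used for G. hirsutum genes, and reads of both species were reported on the same identifiers. Every listed gene was above 0 in at least 1 library. The identifiers fall into 27435 on A chromosomes, 29220 on D chromosomes and 2351 on unplaced scaffolds, read from the identifier itself.

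Columns were matched to samples by title. Stages were taken from the sample descriptions, and the number 25 in the titles of the last stage was tried as an alternative age. No gene names were used: 0 identifiers matched the reference table of 74561 G. barbadense genes, in which 0 genes carry a symbol other than the locus tag. The 30 gene lists (wall, cytoskeleton, lipid, hormone, transcription factor and other-tissue genes) fixed before the data were examined could therefore not be matched, and their tests were not run. Markers of other seed tissues could not be looked at for the same reason. Genes were named by a rule fixed at the same time: the largest changes past the threshold that go the same way at all 4 stages (species) or in both species (age), with a highest RPKM of at least 5, the largest by size where none passed, and the largest ratios at each stage, in each case 2 per direction because the identifiers have no names. The 20 most abundant genes, subgenomes, chromosomes, near-equal pairs, peak stages and library correlations were chosen after the data were seen.

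RPKM values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment, for the 20356 genes with a mean of at least 1 RPKM over the 8 libraries. A change on this scale understates that of low genes. The additive model held species and stage as factors (3 residual degrees of freedom), so a species difference is judged against its variation between stages and a stage difference against its variation between species. The slope model held species, age in days and their product (4 residual degrees of freedom). The stage factor pairs the libraries by design, each stage holding 1 library of each species. Nothing in the labels says how many plants a library came from, and the p-values measure only the spread between these libraries. At a single stage only ratios are given, with a count of genes at least 4-fold apart and at 5 RPKM or more in the higher library. Other computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

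The library size used in the scaling, called relative depth here, was read from the steps of the low values. For 75.2% of the 40389 genes with 4 or more values above 0, the low values were whole multiples of 1 step within 0.15 reads, against 4.81% after each value was multiplied by a random factor. The relative depths were 1.00, 0.982, 0.983 and 1.12 at 5, 10, 15 and 20 DPA in G. barbadense and 0.975, 1.00, 1.01 and 1.16 in G. hirsutum, relative to the first. The reads recovered in those genes numbered from 168656 (G. hirsutum, 5 DPA) to 692133 (G. barbadense, 10 DPA), over genes holding 20.6% to 34.5% of the summed RPKM. At a median of 0.152 RPKM per read, values under 1 RPKM rest on few reads, and a value of 0 on none. Because the summed RPKM differed 3.64-fold between libraries of like size in the scaling, results are given as deposited and after rescaling. The median-of-ratios factors, from 15529 genes above 0 in all libraries, were 1.32, 2.03, 1.14 and 0.742 in G. barbadense and 0.593, 1.26, 0.984 and 0.737 in G. hirsutum.

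The models were tested on simulated log2 values for 20356 genes of which 200 were changed. For a species difference 99% of 16-fold and 0% of 4-fold changes were recovered, for 20 against 5 DPA 84% and 0%, and for the species difference in the change with age 0% and 0%. The 16-fold runs gave 17, 9 and 0 false calls in these 3 comparisons. No shift common to a whole library was simulated. In the data, genes passed at species differences down to 1.52 on the log2 scale, so these rates hold for the simulated setting only. The depth estimate was tested on simulated reads, with a largest error of 0.1%. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 RPKM, both rescalings, each library left out, the model without stage, and those named in the closing section.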

Results

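Transcript levels were measured by RNA sequencing in developing fibers of 2 cultivated tetraploid cottons, Gossypium hirsutum (upland cotton) and Gossypium barbadense (the extra-long-staple cotton). A cotton fiber is a single seed-coat cell that first elongates and then lays down a cellulose-rich secondary wall, and both species carry an A and a D subgenome. Fibers were taken at 5, 10, 15 and 20 days post anthesis (DPA), with 1 library per species and stage, 8 libraries in all. The last stage is labelled 20 DPA in the sample descriptions, whereas the sample titles carry the number 25; it is called 20 DPA here. No stage was replicated within a species, so species were tested across the 4 stages, and stages across the 2 species. The p-values below therefore rest on how evenly a difference recurred over those libraries.

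The 8 libraries differed in the RPKM summed over the 59006 listed genes. The summed RPKM in G. barbadense was 258680 at 5 DPA, 503585 at 10 DPA, 380030 at 15 DPA and 324181 at 20 DPA. In G. hirsutum it was 138198, 326872, 252850 and 298338 at the same stages. The steps between low RPKM values showed that 1 read was worth nearly the same in every library: the library sizes used in the scaling lay between 0.975 and 1.16 relative to G. barbadense 5 DPA. One read was worth a median of 0.152 RPKM. The number of genes at 1 RPKM or more was 23850, 27539, 19140 and 11646 at 5, 10, 15 and 20 DPA in G. barbadense and 13050, 18158, 14607 and 12319 in G. hirsutum. The 100 most abundant genes took 19.9% of the summed RPKM at 5 DPA and 48.0% at 20 DPA in G. barbadense, and 25.6% and 45.5% in G. hirsutum.

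**Figure D1:**
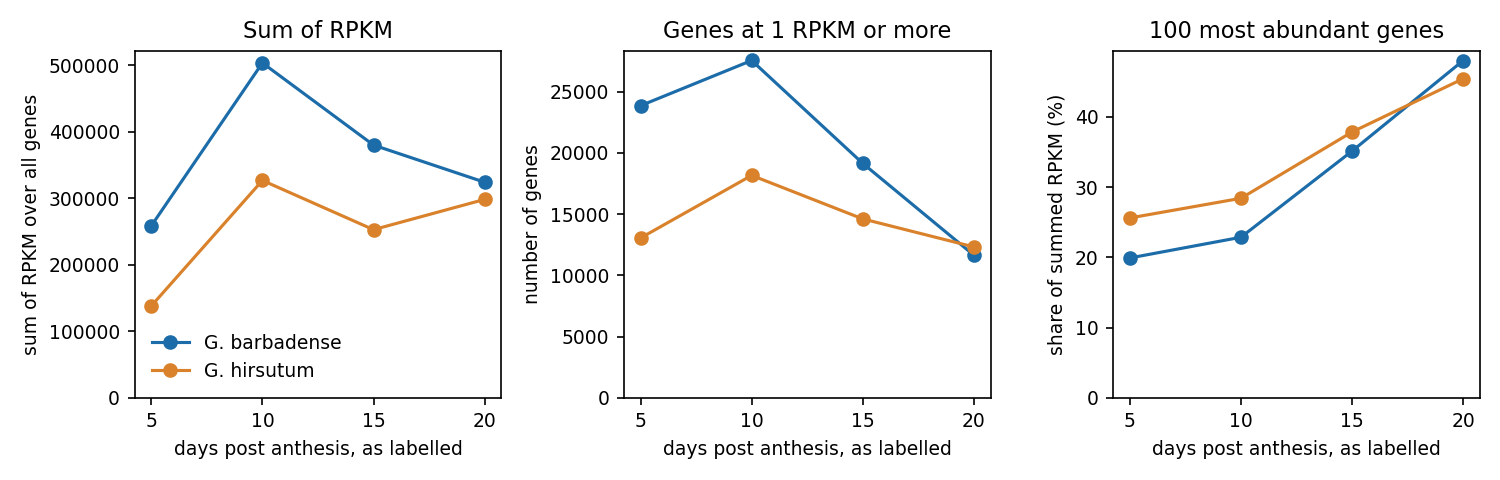
Summed RPKM, number of genes at 1 RPKM or more, and percent of summed RPKM held by the 100 most abundant genes, against days post anthesis as labelled; each point is 1 library and the colours are the species. The G. barbadense sums exceed those of G. hirsutum at each stage, by 1.87-fold at 5 DPA and 1.09-fold at 20 DPA.

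Gene names could not be attached to the identifiers, so genes are given by identifier, subgenome and chromosome. An identifier such as Gh_A09G1166 places the gene on chromosome A09, and the Sca identifiers lie on unplaced scaffolds. The 20 genes with the highest mean RPKM were chosen after their values were seen. Of these 20 genes, 4 were higher in G. barbadense, 3 of them at similar levels in each library. The other was Gh_Sca192591G01 (log2 difference 2.03, SE 0.46, limma adjusted p = 0.0464), which missed the threshold after rescaling (adjusted p = 0.167 and 0.138). Gh_A09G1166, Gh_D09G1172 and Gh_Sca222153G01 stood at 3139, 3261 and 3176 RPKM in G. barbadense at 5 DPA, against 129, 133 and 133 RPKM in G. hirsutum. At 10 DPA Gh_A09G1166 stood at 7412 RPKM against 368 RPKM, and at 20 DPA at 5711 RPKM against 1608 RPKM. Over the 4 stages Gh_A09G1166 was higher in G. barbadense by 3.85 on the log2(RPKM + 1) scale (SE 0.40, 4 libraries per species; limma, Benjamini-Hochberg adjusted p = 0.000868). The difference was 3.34 after rescaling by median-of-ratios factors (adjusted p = 0.0155) and 3.60 after quantile normalization (adjusted p = 0.0188).

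Among the same 20 genes, Gh_D10G1142, Gh_A10G1332 and Gh_A09G2303 were higher in G. hirsutum. Gh_D10G1142, the most abundant gene in the G. hirsutum libraries at 5 and 15 DPA, stood at 4682 RPKM at 5 DPA and 11652 RPKM at 15 DPA there, against 299 and 5182 RPKM in G. barbadense. Its species difference was -1.91 (SE 0.39, limma adjusted p = 0.0362). Gh_A10G1332 was lower in G. barbadense by a similar amount (-1.61, SE 0.34, limma adjusted p = 0.0397). Both directions held under the other scalings, where neither gene passed the threshold (adjusted p from 0.0833 to 0.118). Gh_A09G2303 was lower in G. barbadense by -1.70 (SE 0.29, limma adjusted p = 0.0224) and passed the threshold under both rescalings (adjusted p = 0.0372 and 0.0204).

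The series asks how the 2 species differ in gene expression during fiber development. Over the 4 stages, 374 of 20356 tested genes differed between the species, 297 higher and 77 lower in G. barbadense (limma with stage as a factor, Benjamini-Hochberg adjusted p under 0.05). The higher genes had a median difference of 2.52 and the lower genes of -2.56 on the log2(RPKM + 1) scale. The sign was the same at all 4 stages for 269 of the higher and 76 of the lower genes. The median gene was itself 0.49 higher in G. barbadense, 0.13 after median-of-ratios scaling and -0.02 after quantile normalization. With median-of-ratios factors 61 genes passed, 15 higher and 46 lower in G. barbadense, and 60 of them were among the 374, in the same direction. Quantile normalization gave 19 higher and 71 lower. The excess of genes higher in G. barbadense among those past the threshold was thus not seen after rescaling. The 297 higher genes had been chosen at a difference of at least 1.52. Their median was 2.15 after median-of-ratios scaling, where 15 of them still passed, and 2.08 after quantile normalization. At an unadjusted p under 0.05 the excess was present as deposited (4789 higher, 610 lower) and with median-of-ratios factors (2752 and 1419). The counts were nearly even with quantile normalization (2220 and 1885). The count also hung on single stages. With stage in the model, leaving out 1 library takes the other library of that stage out of the species estimate too. Leaving out any 1 library of 5, 10 or 15 DPA left 13 to 31 genes. Leaving out both 20 DPA libraries gave 2988 (2811 higher, 177 lower), or 0 with median-of-ratios factors.

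By the fixed naming rule, the largest differences were those of Gh_A06G0930, Gh_D05G2546, Gh_A13G2209 and Gh_A06G0608. Gh_A06G0930 stood at 29.3, 115, 197 and 50.2 RPKM at the 4 stages in G. barbadense and at 0.29, 1.41, 0 and 10.7 RPKM in G. hirsutum (log2 difference 4.97, SE 0.70, limma adjusted p = 0.00841). Gh_D05G2546 stood between 14.6 and 31.6 RPKM in G. barbadense, and in G. hirsutum it was listed at 0 before 20 DPA and at 1.49 RPKM at 20 DPA (limma adjusted p = 0.00418). In the other direction, Gh_A13G2209 was listed at 0 in every G. barbadense library and stood at 18.8, 56.3, 24.6 and 6.13 RPKM in G. hirsutum (limma adjusted p = 0.00317). Gh_A06G0608 was also listed at 0 in every G. barbadense library and reached 261 RPKM in G. hirsutum at 20 DPA (limma adjusted p = 0.0224). Chosen for a large difference of the same sign at all 4 stages, these genes could hardly change direction, and none did in 16 alternative settings. Each of the 4 genes missed the threshold in 4 to 8 of these settings.

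The genes that differed between the species lay on both subgenomes. Of the tested genes, 1.22% of those on A chromosomes and 1.53% of those on D chromosomes were higher in G. barbadense (Fisher's exact test, two-sided p = 0.0749), and 0.39% and 0.34% were lower (p = 0.635). Unplaced scaffolds held 28 of the higher genes against 12.2 expected from their size (Fisher's exact test, adjusted p = 0.00117 over 27 chromosome groups). Chromosome A06 held 1 against 9.19 expected (Fisher's exact test, adjusted p = 0.0254). These tests count genes as independent and use the calls as deposited. Of the 297 higher genes, 15 still passed after median-of-ratios scaling, and the tests were not repeated there. The scaffold identifiers took 7.36% ± 0.49 of the summed RPKM in G. barbadense and 5.44% ± 0.34 in G. hirsutum (SD over the 4 stages), with G. barbadense higher at all 4 stages (exact sign-flip test by stage, two-sided p = 0.125, the smallest this design allows). Without the 3 scaffold identifiers among the 20 most abundant genes the shares were 4.57% ± 0.81 and 4.31% ± 0.58. The difference was smaller, but G. barbadense was still higher at all 4 stages (exact sign-flip test, p = 0.125). The A subgenome share was 45.4% ± 0.57 in G. barbadense and 46.7% ± 0.69 in G. hirsutum, lower in G. barbadense at every stage (exact p = 0.125).

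Stage by stage, with 1 library on each side and hence no replicate check, the species stood closest at 20 DPA. Among genes reaching 5 RPKM in either species, 2869 were at least 4-fold higher in G. barbadense and 389 in G. hirsutum at 5 DPA, on the log2(RPKM + 1) scale. The counts were 2609 and 337 at 10 DPA, 2315 and 500 at 15 DPA, and 130 and 351 at 20 DPA. With median-of-ratios factors they became 1134 and 1209 at 5 DPA, 793 and 492 at 10 DPA, 1923 and 614 at 15 DPA, and 174 and 453 at 20 DPA. The genes reaching 5 RPKM, from which these counts come, numbered 8686, 12382, 8864 and 5877 at the 4 stages as deposited. With median-of-ratios factors they numbered 8585, 8274, 8419 and 7038, so fewest were eligible at 20 DPA under both scalings. The smaller number of genes 4-fold apart at 20 DPA and the excess towards G. barbadense at 10 and 15 DPA were present under both scalings. The excess at 5 DPA was present only as deposited. Across genes, which are not independent replicates, the species ratio at 10 DPA correlated with that at 15 DPA (Spearman's rho 0.59). The ratio at 20 DPA correlated with those of the earlier stages at 0.09 to 0.15.

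**Figure D2:**
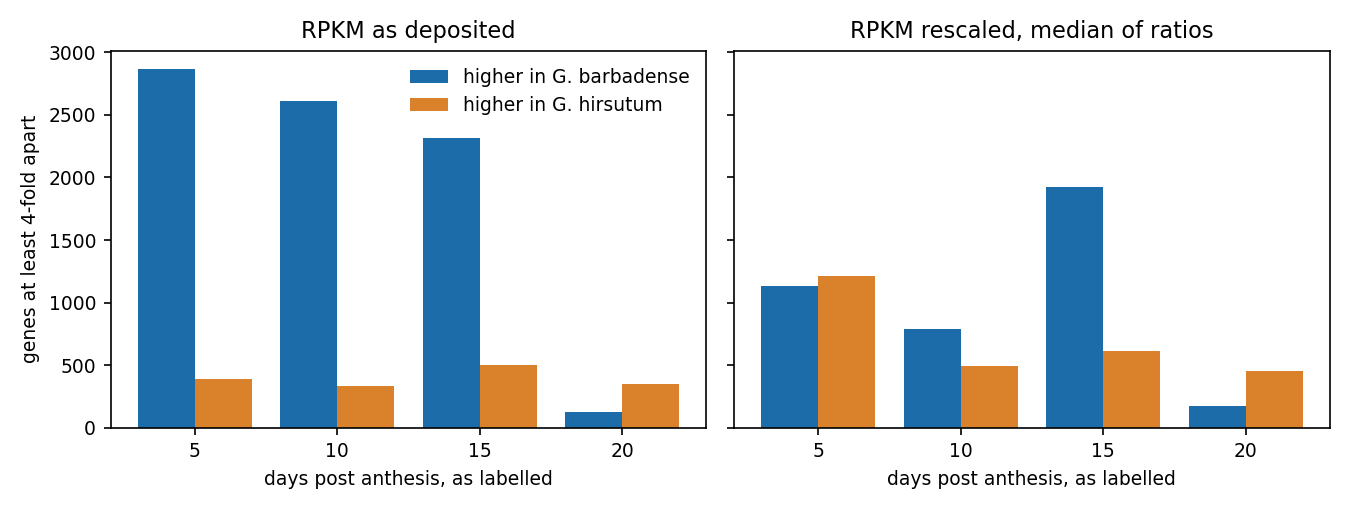
Number of genes at least 4-fold apart between the species (vertical axis) at each stage in days post anthesis (horizontal axis), among genes reaching 5 RPKM in either library; blue bars are genes higher in G. barbadense, orange bars genes higher in G. hirsutum, left for RPKM as deposited and right after median-of-ratios scaling. The blue and orange bars together are lowest at 20 DPA in both panels, and the 2869 blue genes at 5 DPA fall to 1134 after rescaling.

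Single stages showed genes that were abundant in one species and listed at 0 in the other. At 5 DPA, Gh_A04G1103 and Gh_Sca027989G01 stood at 93.9 and 88.3 RPKM in G. barbadense and at 0 in G. hirsutum, while Gh_D08G0414 and Gh_A08G0316 stood at 707 and 740 RPKM in G. hirsutum and at 8.42 and 9.02 RPKM in G. barbadense. At 10 DPA, Gh_D04G0445 and Gh_A05G2550 stood at 111 and 75.9 RPKM in G. barbadense and at 0 in G. hirsutum, and Gh_A02G0236 and Gh_D12G0757 at 83.6 and 123 RPKM in G. hirsutum against 0 and 0.49 RPKM. At 15 DPA, Gh_A06G0930 and Gh_D13G1994 stood at 197 and 176 RPKM in G. barbadense alone, and Gh_A02G0668 and Gh_A01G0338 at 57.2 and 53.4 RPKM in G. hirsutum alone. At 20 DPA, Gh_D13G1380 and Gh_D08G1025 stood at 111 and 142 RPKM in G. barbadense against 0 and 1.24 RPKM, and Gh_D06G0690 and Gh_A06G0608 at 405 and 261 RPKM in G. hirsutum against 0.

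A stricter question is which genes were seen at every stage in one species and at no stage in the other. At 5 RPKM or more in all 4 libraries of one species and at most 0.1 RPKM in all 4 of the other, 4 genes were seen in G. hirsutum alone and 0 in G. barbadense alone. The 4 were Gh_D08G1946 (16.5 to 25.4 RPKM in G. hirsutum), Gh_A07G1707 (6.59 to 20.2 RPKM), Gh_A13G2209 (6.13 to 56.3 RPKM) and Gh_D02G2035 (5.81 to 8.15 RPKM). At a minimum of 1 RPKM the numbers were 19 in G. hirsutum alone and 14 in G. barbadense alone. All 33 were listed at exactly 0 in the other species. The identifiers have the form used for G. hirsutum genes, so a 0 in G. barbadense does not show that the gene was silent. A G. barbadense gene without such an identifier could not be counted. Without the 20 DPA library of G. barbadense the counts at 5 RPKM were 5 in G. hirsutum alone and 6 in G. barbadense alone, and no test applies to them.

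The level of 1551 genes differed between stages over the 2 species (limma F-test over the 3 stage terms, Benjamini-Hochberg adjusted p under 0.05). Between 5 and 20 DPA, 688 genes rose and 529 fell. The rising genes had a median log2 change of 3.38 in G. barbadense and 3.57 in G. hirsutum, and the falling genes of -3.66 and -2.74. The 688 rising genes, which were chosen on these same libraries, took 8.20% of the summed RPKM at 5 DPA and 52.5% at 20 DPA in G. barbadense, and 7.12% and 48.9% in G. hirsutum. The 529 falling genes went from 8.55% to 0.29% and from 10.2% to 0.28%. The split was 1021 rising and 674 falling with median-of-ratios factors and 888 and 438 with quantile normalization. The median gene changed by -0.49 as deposited, -0.35 with median-of-ratios factors and -0.08 with quantile normalization. The split moved both ways in the alternatives, from 690 rising and 989 falling with a pseudocount of 0.1 to 288 and 31 without the 20 DPA library of G. barbadense.

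The step from 15 to 20 DPA held most of the genes past the threshold. From 15 to 20 DPA 241 genes rose and 88 fell, from 5 to 10 DPA 7 rose and 3 fell, and from 10 to 15 DPA 0 rose and 1 fell (limma, adjusted p under 0.05). At an unadjusted p under 0.05 these steps gave 2982, 3054 and 1634 genes as deposited. For the last and the first step they gave 3014 and 1201 with median-of-ratios factors and 2205 and 1394 with quantile normalization. In the median-of-ratios values the numbers past the adjusted threshold were 368 for the last step and 0 for the other steps.

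Several of the most abundant genes that rose from 5 to 20 DPA came as an A and a D identifier with nearly the same level. Gh_Sca131739G01 also rose, by 3.87 on the log2 scale (SE 0.53, limma adjusted p = 0.000769), and was in no such pair. Gh_A06G0811 and Gh_D06G0940 stood at 975.4 and 903.9 RPKM at 5 DPA and at 13954 and 13431 RPKM at 20 DPA in G. barbadense, and went from 370 and 372 RPKM to 8660 and 8642 RPKM in G. hirsutum. Their log2 rise was 4.19 (SE 0.45, limma adjusted p = 0.000109) and 4.21 (SE 0.44, adjusted p = 9.73e-05). Gh_A03G1623 and Gh_D02G2038 rose by 4.42 and 4.39 (SE 0.48 and 0.49; limma adjusted p = 0.000121 and 0.000143) and reached 12142 and 11999 RPKM in G. hirsutum at 20 DPA. Gh_A05G1347 and Gh_D05G1514 rose by 2.80 and 2.75 (limma adjusted p = 0.000426 and 0.000456) and were highest at 15 DPA in both species. None of these 3 gene pairs differed detectably between the species (adjusted p from 0.54 to 0.82). Gh_A10G1331 went the other way, from 554 and 1138 RPKM at 5 DPA to 69.3 and 64.9 RPKM at 20 DPA in G. barbadense and G. hirsutum (log2 change -3.55, SE 0.45, limma adjusted p = 0.000437).

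The largest rises by the fixed naming rule were those of Gh_A02G0316 and Gh_A08G0457. Gh_A08G0457 was listed at 0 at 5, 10 and 15 DPA in both species and stood at 1279 RPKM in G. barbadense and 3688 RPKM in G. hirsutum at 20 DPA (limma adjusted p = 3.76e-06). Gh_A02G0316 was listed at 0 at 5 DPA in both species and stood at 2126 and 3578 RPKM at 20 DPA (limma adjusted p = 1.01e-05). The largest falls were those of Gh_D08G1166 and Gh_Sca115726G01. Gh_D08G1166 fell from 139 RPKM in G. barbadense and 42.5 RPKM in G. hirsutum at 5 DPA to values listed at 0 at 20 DPA (limma adjusted p = 0.00095). Gh_Sca115726G01 fell from 210 and 150 RPKM to 1.81 and 1.75 RPKM (log2 change -6.00, SE 1.01, limma adjusted p = 0.00306). Both rising genes passed the threshold in all 13 alternative settings, and the falling genes missed it in 2 and 3 of them.

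**Figure D3:**
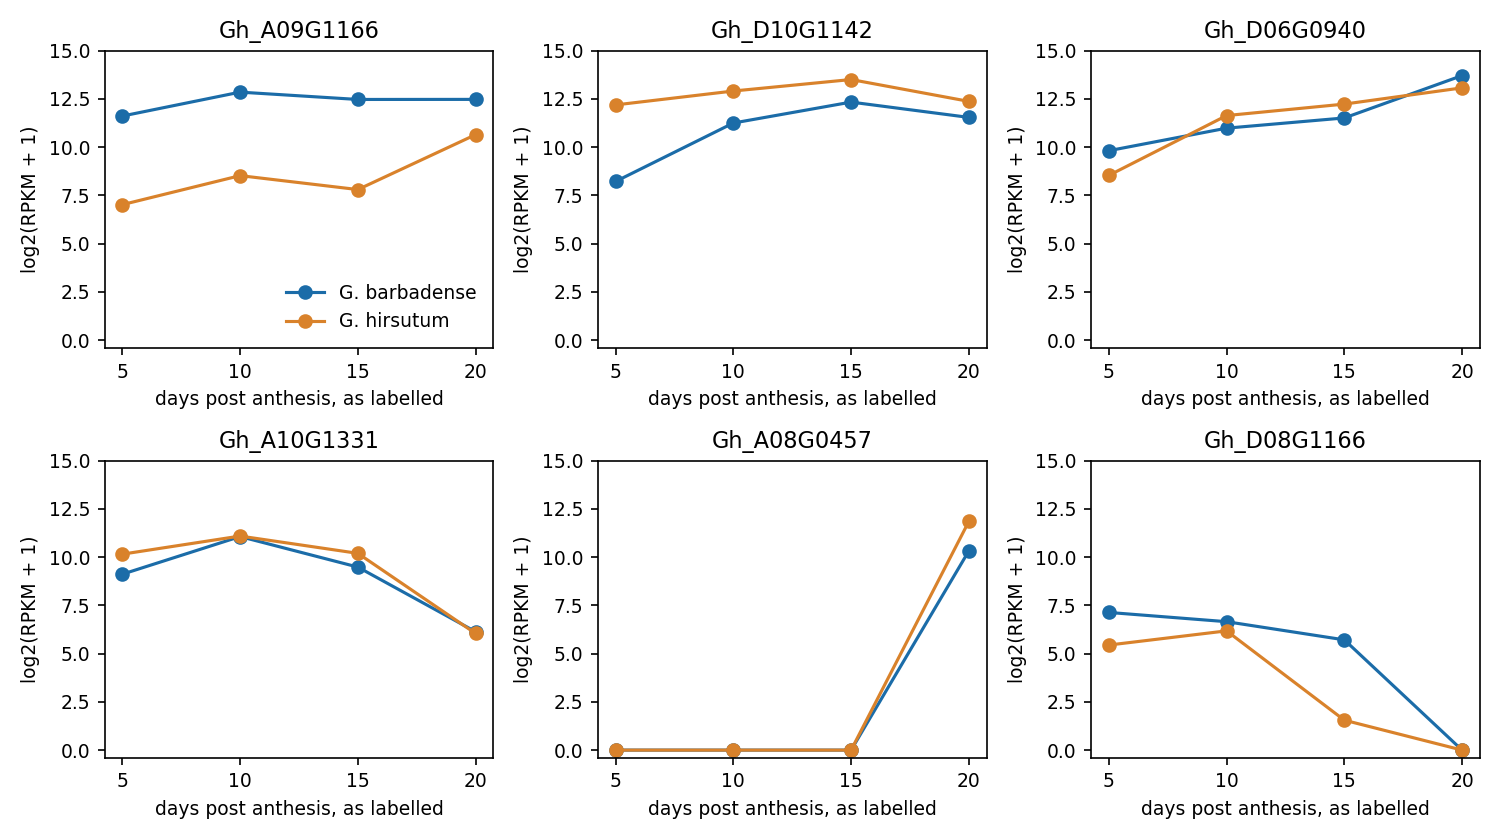
Time courses of 6 genes, as log2(RPKM + 1) against days post anthesis as labelled; each point is 1 library and the colours are the species. Gh_A09G1166 lies higher in G. barbadense and Gh_D10G1142 higher in G. hirsutum at each stage, Gh_D06G0940 and Gh_A08G0457 reach their highest level at 20 DPA, and Gh_A10G1331 and Gh_D08G1166 their lowest.

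Genes that rose with age were found at like rates on both subgenomes, 3.27% of A and 3.50% of D genes (Fisher's exact test, two-sided p = 0.384), and so were genes that fell, 2.34% and 2.65% (p = 0.184). Unplaced scaffolds held 41 falling genes against 21.7 expected (Fisher's exact test, adjusted p = 0.00341). Genes were again counted as independent. Genes tended to be highest at the same stage in both species: 9692 of 20356 genes (47.6%) were, against 35.9% expected from how often each stage was the highest in each species. At 20 DPA 1609 genes were highest in both species against 440.2 expected, at 10 DPA 6775 against 5915. After median-of-ratios scaling the shared share was 39.0% against 25.4% expected. The count at 10 DPA was then 1990 against 1527.8 expected, and at 20 DPA 3146 against 1370.7, so 10 DPA held the most shared peaks only as deposited.

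The libraries of the 2 species were most alike at 20 DPA, with a Spearman's rho across genes of 0.80, against 0.46 at 5 DPA, 0.61 at 10 DPA and 0.46 at 15 DPA. Among the libraries of the other species, those of G. barbadense at 5 and 15 DPA were closest to G. hirsutum at 10 DPA (rho 0.54 and 0.65), and G. hirsutum at 15 DPA was closest to G. barbadense at 20 DPA (rho 0.66). Within its own species, G. barbadense 15 DPA was closer still to 10 DPA (rho 0.78), and G. hirsutum 15 DPA to 10 and 20 DPA (rho 0.73 and 0.72). G. barbadense 20 DPA did not follow this: its rho with 5, 10 and 15 DPA of its own species was 0.34, 0.30 and 0.47. With G. hirsutum at 10, 15 and 20 DPA it was 0.53, 0.66 and 0.80. The value of 0.80 also lay above every pair within a species (highest 0.78). These values describe 8 single libraries.

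**Figure D4:**
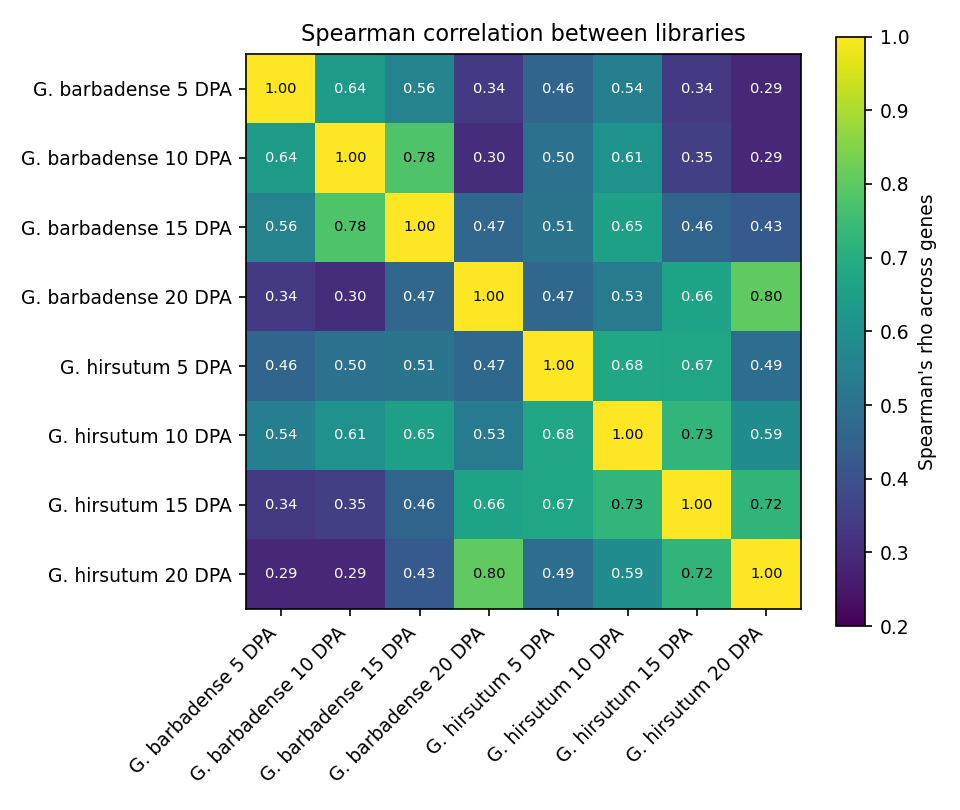
Spearman's rho across the 20356 tested genes for each pair of libraries, with species and stage on both axes and the value in each cell (colour scale from 0.2 to 1). The 20 DPA libraries of both species give 0.80, above the other pairs that join the species.

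Whether expression changed with age differently in the 2 species was tested by the product of species and age. At an adjusted p under 0.05 no gene passed (0 of 20356, limma; smallest adjusted p 0.945), and 734 genes had an unadjusted p under 0.05, of which 668 had the lower slope in G. barbadense; after rescaling the directions were nearly even (531 higher and 614 lower with median-of-ratios factors, 545 and 533 with quantile normalization). The simulated data had 200 changed genes among 20356 and noise taken from the additive model. There the same fit found 0% of genes whose species ratio grew 16-fold from 5 to 20 DPA. A count of 0 genes thus does not show that such differences are absent. Settings with more changed genes were not simulated. The largest slope differences are given as values only. Gh_D13G1380 went from 2.69 to 111 RPKM in G. barbadense and from 13.8 to 0 RPKM in G. hirsutum between 5 and 20 DPA (unadjusted p = 0.00286). Gh_D08G1025 went from 2.87 to 142 RPKM and from 11.04 to 1.24 RPKM (unadjusted p = 0.011). Gh_D04G0416 went from 100.08 to 0 RPKM in G. barbadense and from 2.58 to 15.2 RPKM in G. hirsutum (unadjusted p = 0.000883), and Gh_D08G0094 from 6.13 to 1.42 RPKM and from 1.28 to 124 RPKM (unadjusted p = 0.00953).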

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

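The tests of scale and depth in this part were chosen after the result was seen. Between 5 and 20 DPA 2 measures of the libraries moved in opposite directions in the 2 species, on 1 library each, so the difference was not tested. The median-of-ratios factor changed by -0.83 on the log2 scale in G. barbadense and by 0.31 in G. hirsutum, and the number of genes at 5 RPKM or more by -0.67 and 0.28. The summed RPKM was higher at 20 than at 5 DPA in both species (0.33 and 1.11), and the number of genes at 1 RPKM or more was lower in both (-1.03 and -0.08).

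Of the 374 genes past the threshold between the species, 297 were higher in G. barbadense. Greater sequencing depth in G. barbadense stays open: the library size used in the scaling was at most 1.026 times that of G. hirsutum at 5, 10 and 15 DPA, but which reads it counts is not given, and the reads in the genes with a known step were 2.67, 2.25 and 1.61 times as many. At 20 DPA these reads were 0.859 times as many. There, 130 genes were at least 4-fold higher in G. barbadense and 351 in G. hirsutum. A library-wide difference in scale stays open. After median-of-ratios scaling 24.6% of the called genes were higher in G. barbadense, against 79.4% as deposited. The 297 higher genes kept their direction. Their median log2 difference was 2.52 (SD 0.48, median SE 0.53) before and 2.15 (SD 0.48, median SE 0.50) after. These genes had been chosen at a difference of at least 1.52, and rescaling moved the median gene from 0.49 to 0.13. Under so small a shift they could hardly flip, so the kept direction cannot tell scale from another cause. Fewer genes then had an unadjusted p under 0.05 (4171 against 5399), and the adjusted threshold depends on that number. Rescaling itself changed that number, so the lost calls cannot show whether scale made these differences. What the reads outside the listed genes were is open, since the table holds none of them, and so is a biological difference in how many genes each fiber expresses.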

How the results depend on the processing

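The 12 named genes kept their direction in all 172 refits, and in 27 of them a gene that had passed the threshold missed it. Many of these refits cannot move the estimate. The species and age genes were also chosen for a large change of the same sign at all 4 stages or in both species. Their kept direction was thus largely fixed in advance. Other counts moved more. The 374 species differences became 54 with a pseudocount of 0.1 (32 higher and 22 lower in G. barbadense), 0 without a filter on low values, 21 at a mean of at least 5 RPKM (10 and 11), 61 with median-of-ratios scaling and 90 with quantile normalization. The causes were not tested. Without the stage pairing (no replicate block) 6 genes passed. Leaving out 1 library takes its whole stage out of the species estimate. It gave from 13 genes (without G. hirsutum 5 DPA) to 3011 (without G. barbadense 20 DPA, 2845 higher and 166 lower). Leaving out G. hirsutum 20 DPA gave 2988 (2816 and 172), and leaving out any of the other 6 libraries left 13 to 31. Without both 20 DPA libraries, an alternative added after the data were seen, 2988 passed, and 0 with median-of-ratios scaling as well. The 1551 stage changes became 68 without a filter, 717 with median-of-ratios scaling, 780 with quantile normalization and 241 with age as a number, and from 105 (without G. barbadense 20 DPA) to 2153 (without G. barbadense 15 DPA) with 1 library left out. The 1217 changes from 5 to 20 DPA became 217 without a filter (185 rising, 32 falling), 472 without G. barbadense 5 DPA (350 and 122), 750 without G. hirsutum 20 DPA (353 and 397), and from 319 (without G. barbadense 20 DPA) to 1397 (without G. barbadense 15 DPA) with 1 library left out. A stage with 1 library left is assumed to vary like the others. Genes 4-fold apart at 10 DPA went from 2946 to 1285 with median-of-ratios scaling. The 4 genes near 0 in one species became 33 at a minimum of 1 RPKM, and 4 to 11 with 1 library left out (11 without G. barbadense 20 DPA, 6 of them in G. barbadense alone, and 7 without G. hirsutum 20 DPA). Genes highest at the same stage in both species were 3954 at a mean of at least 5 RPKM, where fewer genes were tested. The slope test gave 0 genes in every alternative, with the last stage at 25 days too. The gene list tests were not run.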

Other observations

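In this part the tests of library scale, exchanged labels and near-equal identifiers were chosen after the result was seen, and those of consecutive identifiers and of other splits before.

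Genes that changed with age also lay side by side. Of the 1150 called genes on chromosomes, 76 had a gene of the next or previous identifier number called in the same direction, against a mean of 22.3 and a highest value of 44 in 1000 random draws of as many tested genes per chromosome (permutation test, p = 0.001, the smallest these draws can give). This suggests clusters of neighbouring genes among the age-changing genes, as a hypothesis; copies that share reads would give the same count, and no sequences were used here. For the species difference the number was 8 of 340, within the draws (mean 2.74, highest 12, permutation test, p = 0.0639). Gh_A10G1332 and Gh_A10G1331 carry consecutive numbers, and between 5 and 20 DPA Gh_A10G1332 went from 348 to 2227 RPKM in G. barbadense and from 3512 to 4185 RPKM in G. hirsutum (limma adjusted p = 0.0901), while Gh_A10G1331 went from 554 to 69.3 RPKM and from 1138 to 64.9 RPKM.

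At 15 DPA the G. hirsutum fiber stood further along the course from 5 to 20 DPA. For 4167 genes that changed at least 2-fold in the same direction in both species, the median position at 15 DPA was 0.56 of the way in G. hirsutum and 0.30 in G. barbadense, and 62.7% of the genes were further along in G. hirsutum. The medians differed in this direction on 26 of 26 chromosomes, though genes of 1 library are not independent. A library-wide difference in scale as the only source of this direction is argued against, since 65.5% of genes selected on ranks within libraries were further along in G. hirsutum. The size of the share varied with scaling and with the direction of change. For rising genes it was 60.65% as deposited, 57.52% with median-of-ratios factors and 69.95% on ranks. For falling genes it was 64.34%, 72.03% and 61.15%. An exchange of the 15 DPA libraries between species is argued against by 41 of 42 genes (97.6%) that the other stages gave as seen in 1 species alone, and an exchange of the 10 and 15 DPA libraries of G. hirsutum by a median position 0.358 higher at 15 DPA. A later onset of the 20 DPA program in G. barbadense is a candidate explanation that stays open, as do the age of the sampled bolls and chance between single libraries.

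Among 1978 genes at 5 RPKM or more in every library, 19 pairs of identifiers lay within 10% of each other in all 8 libraries, and 8 of the 20 most abundant genes were among them. Chance resemblance of profiles is argued against: 100% of the pairs joined corresponding A and D chromosomes, counting the known A02-A03 and A04-A05 exchanges, against 4.64% of all pairs. Reads shared between near-identical copies may account for the 19 pairs. That and equal expression of both copies cannot be told apart here, because no sequences were used and the counting rule is not given. The A and D values of such pairs can therefore not be counted as independent measurements here.

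The 374 species differences were compared with other splits of the 8 libraries into 4 and 4, with stage in the model. Of the 32 splits that could be fitted, 1 gave as many genes, the real one, and the highest other gave 0. Most of the others part only 2 stages, which leaves the species difference in the residual, so the bound of 5% set for these splits was wrong for this paired design. The 8 splits that part every stage are too few for a share under 5%; the highest other of these gave 0. For the slope difference all 35 of 35 splits gave as many as the real count of 0, and the highest gave 50. Any split gives at least 0, so this comparison decides nothing.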
